A study of Mus musculus with 43 samples.

How the data were processed

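RNA was taken from 43 mouse samples in 15 groups: 9 cultures of brown adipocytes with overexpression, 12 with knockouts, 4 with full-length or shortened Runx2, and 18 samples of inguinal fat. Per the submitters' processing notes, reads were trimmed with fastp, aligned to the mm39 mouse genome with STAR and counted per gene with featureCounts, with no versions or options given. The values used are the deposited raw counts per gene symbol, 1 column per library in 6 tables, with no scaling applied, per the file headers. The values on the log2 scale in the deposited lists of changed genes are fold changes of the submitters' own comparisons, per the file headers. The adjusted p-value in those lists is likewise deposited by the submitters, whose column names are those of a DESeq2 table. The HFD list goes up to an adjusted p of 0.00992 and down to an absolute log2 fold of 1.02, and the IDR list up to 0.0491 and down to 0.27.

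Library totals ran from 28.1 to 52.2 M counts. Of values from 1 to 19, 71.1 to 81.9% were even, so both reads of a pair may have been counted singly, and counting intervals, which cover counting error only, would then be too narrow. The gene annotation at hand was of another build, so no positions are given. Symbols were used as in the tables, and the counting may have split reads between near-identical genes. The tables held no mitochondrially encoded genes.

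Groups followed the labels. Each table was fitted on its own in edgeR 4.0.16 under R 4.3.3, with filterByExpr, TMM scaling and the robust quasi-likelihood (QL) test. Benjamini-Hochberg adjustment ran over all tested genes, and a gene was called at adjusted p < 0.05. The 15 contrasts were: each perturbed group against its control, groups of the same table against each other, the departure of the double knockout from the sum of the single knockouts, and 2 differences between knockout effects in separate iWAT tables. Those last 2 joined tables in 1 fit, so table and condition cannot be separated there. Log2 fold changes are edgeR's, with a standard error from the fit, and CPM are scaled by TMM except in the plots.

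A set of 34 gene lists, written before the data were examined like the contrasts and the naming rule, was tested with camera of limma 3.58.1 on voom values at the preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. Lists with fewer than 3 tested genes were left out, among them B cell genes in all cultures. Called genes of a list were also counted with p-values adjusted over the list alone. List calls were repeated under the alternatives for the 9 comparisons with a control, and with all libraries only for the others. Sets for comparing tables were genes called at 2-fold or more in another table.

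Genes were named by a rule. It takes Runx1, Runx2, Runx3 and Cbfb everywhere and, against a control, Ucp1, Cidea, Dio2, Ppargc1a, Cox8b, Elovl3, Prdm16, Pparg, Adipoq, Fabp4, Plin1, Lep, Col1a1 and Postn. It adds the 6 called genes with the highest and the 6 with the lowest fold change among those with mean CPM of at least 5 and no overlap between groups (4 each way in other contrasts), leaving out predicted, mitochondrial and antigen receptor genes. For each called list it takes up to 3 called members of lowest adjusted p in its direction and 1 in the other. Chance leaves groups of 3 without overlap in 10% of genes. The text gives a part of the genes so picked; 2 withheld for evaluation are not reported here. Dio2 fell under the count filter in the cultures.

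Shared controls were modelled with 10 simulations without effect. The whole procedure was tested on simulated counts with 200 genes changed: at 2-fold 12 to 88% were recovered in the 9 comparisons with a control (fewest in Runx2 knockout iWAT), at 4-fold 75 to 93%, with 0 of wrong sign, and 3.31 to 7.91% of calls were false.

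Alternatives were DESeq2 1.42.0 scaling or testing, no count filter, the replicate number as a block, each library left out in turn, a fit of the compared groups alone, fry, and the thermogenic list without Ucp1. Chosen after seeing the data were fits with a score of B cell or skeletal muscle genes as a covariate, and fits without libraries that carried cardiac or skeletal muscle transcripts. The 10 per-sample columns of the deposited lists, whose unit no header states, were used only to match libraries. They number some libraries otherwise than the count tables, but in the same order each agrees within 0.001% with the CPM of a count column, for all genes found in both. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.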

Results

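Polyadenylated RNA was sequenced from 43 mouse libraries in 15 groups, held in 6 count tables of 26264 genes each. Totals ran from 28.1 to 52.2 M counts per library. RUNX1 and RUNX2 are transcription factors known from blood and bone formation that bind DNA together with CBFB. Brown preadipocytes had received an empty vector, Runx1 or Runx2 before differentiation, or had been knocked out for Runx1, Runx2, both or neither, with 3 libraries per group. Inguinal white fat (iWAT) came from Runx1-floxed and Runx2-floxed mice with or without Adipoq-cre, and from wild-type and Runx1 knockout mice labelled HFD, again with 3 libraries per group. A last table held cultures with full-length Runx2 and cultures with Runx2 lacking a part labelled IDR, 2 libraries per group. The series title speaks of more beige fat after loss of either factor, so a thermogenic gene list with Ucp1 was read first in each comparison. Values are log2 fold changes with standard errors (SE), or group means ± SD in CPM, counts scaled to the library total. Genes were called at edgeR QL adjusted p < 0.05 and lists at camera adjusted p < 0.05. The labels do not say whether libraries came from separate cultures or animals, so all p-values measure only the spread between libraries. In each gene said to have risen or fallen, every library of the changed group lay beyond every control library unless stated.

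Runx1 mRNA rose 13.2-fold in the cultures given Runx1 (73.9 ± 10.5 against 5.57 ± 1.23 CPM, log2 3.72, SE 0.17), and Runx2 mRNA rose 35.2-fold in those given Runx2 (309 ± 25.8 against 8.77 ± 0.892 CPM, log2 5.14, SE 0.12). Each gene also rose with the other, Runx1 to log2 2.44 (SE 0.17) under Runx2 and Runx2 to 0.94 (SE 0.11) under Runx1, and Cbfb rose slightly in both (log2 0.44 and 0.46). In the knockout cultures the mRNA of the named gene was not called lower. Runx1 was at 5.43 ± 1.13 against 5.24 ± 2.62 CPM in the Runx1 knockout, Runx2 at 7.61 ± 0.956 against 7.71 ± 1.28 CPM in the Runx2 knockout. The double knockout had 4.72 ± 1.55 and 7.55 ± 1.39 CPM. A small deletion can leave the count of a gene unchanged, so these counts neither show nor exclude the loss of either protein. In iWAT, Runx1 was at log2 -0.62, SE 0.19 in its knockout (edgeR QL adjusted p = 0.078), Runx2 at log2 -1.19, SE 0.54 in its own (edgeR QL adjusted p = 0.25), and Runx1 at log2 -0.30, SE 0.32 under HFD (edgeR QL adjusted p = 0.95). None of these 3 passed. Falls of like size were seen for the other factor: Runx1 was at log2 -1.28 (SE 0.33) in the Runx2 knockouts. Runx2 was at -0.58 (SE 0.25) in the Runx1 knockouts, but at 0.53 (SE 0.33) under HFD. These did not pass either, and cells other than adipocytes also express both genes. Runx2 fell in the cultures with the shortened form (129 ± 20.2 against 294 ± 0.885 CPM, log2 -1.19, SE 0.085), and a gene-level count cannot tell a missing part from fewer transcripts.

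**Figure D1:**
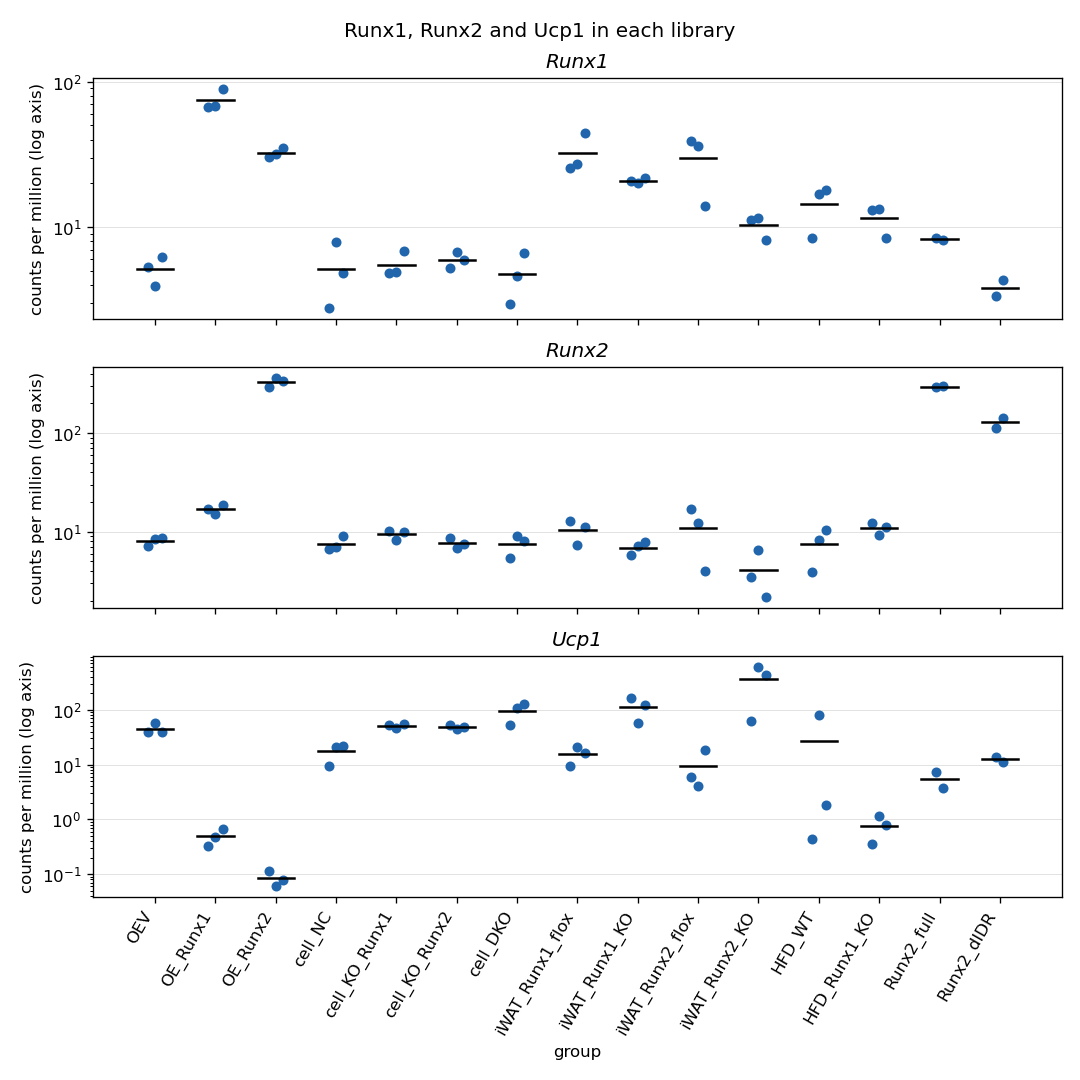
Runx1, Runx2 and Ucp1 in each library, in CPM on log axes, with bars at group means. Group means of Ucp1 were lowest in the cultures given Runx1 or Runx2.

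With Runx1 overexpressed, most thermogenic genes fell and most matrix, osteochondrogenic and interferon genes rose (n = 3 per group). None of these lists passed with an estimated correlation (adjusted p = 0.13 to 0.35). Ucp1, the uncoupling protein of brown fat, fell 102-fold (0.481 ± 0.16 against 48.8 ± 12.5 CPM, log2 -6.67, SE 0.26, edgeR QL adjusted p = 1.8e-08). Cidea, a lipid droplet protein of brown adipocytes, fell by 5.10 log2 units (SE 0.35), and Prdm16, a coregulator of brown-fat identity, fell by 3.18 log2 units (SE 0.25). The matrix glycoprotein Tnc rose to log2 6.22 (SE 0.31) and Sp7, an osteoblast transcription factor, to 5.69 (SE 0.39). In all, 7912 of 14661 tested genes changed, 4134 higher and 3778 lower, of which 1919 and 1161 at least 2-fold.

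Thermogenic genes had 1 of 20 higher and 13 lower (the same adjusted over the list alone, median log2 -1.18, camera adjusted p = 1.0e-05), or adjusted p = 0.35 with an estimated correlation. The brown-fat transcription factor Ebf2, the potassium channel Kcnk3 and the coactivator Ppargc1a fell to log2 -2.22 (SE 0.12), -2.32 (SE 0.13) and -1.28 (SE 0.25). General adipocyte genes did not pass as a group (7 of 25 higher and 11 lower, the same adjusted over the list alone, median log2 -0.088, camera adjusted p = 0.28). Pparg and the droplet coat gene Plin1 fell (log2 -0.47 and -0.62), the adipokine Adipoq rose (log2 0.47), and Fabp4 did not pass (log2 -0.027, SE 0.12). Fatty acid oxidation genes had 2 of 24 higher and 19 lower (the same adjusted over the list alone, median log2 -0.62, camera adjusted p = 3.2e-05). Hadhb was at log2 -1.30 and the acyl-CoA synthetase Acsl1 the other way at 0.98. TCA cycle and respiratory chain lists were lower as well (medians log2 -0.65 and -0.31, camera adjusted p = 4.0e-06 and 4.8e-05). The respiratory chain gene Ndufv3 was at log2 -1.25. Glycolytic and hypoxia-induced genes had 1 of 17 higher and 16 lower (the same adjusted over the list alone, median log2 -1.91, camera adjusted p = 2.8e-11). The mitophagy receptor Bnip3, Ndrg1 and the collagen prolyl hydroxylase P4ha1 fell to log2 -3.02 (SE 0.15), -2.44 (SE 0.11) and -2.19 (SE 0.097). Unfolded protein genes had 1 of 17 higher and 11 lower (the same adjusted over the list alone, median log2 -0.56, camera adjusted p = 0.0023). The chaperone Hspa5 was at log2 -1.19. For these 5 lists adjusted p = 0.13 to 0.60 with an estimated correlation.

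Extracellular matrix genes had 29 of 36 higher and 1 lower (the same adjusted over the list alone, median log2 1.46, camera adjusted p = 3.5e-10) with Runx1. Fmod, the protease Mmp14 and Col1a1 rose to log2 7.19 (SE 0.30), 2.91 (SE 0.16) and 1.85 (SE 0.26). Osteochondrogenic genes had 19 of 24 higher and 2 lower (the same adjusted over the list alone, median log2 2.94, camera adjusted p = 2.4e-05). Alkaline phosphatase Alpl was at log2 1.52 and Col11a1 the other way at -2.14. Interferon genes had 20 of 22 higher and 0 lower (21 and 0 adjusted over the list alone, median log2 2.56, camera adjusted p = 1.5e-09). Ifit1 and Usp18 were at log2 4.19 and 4.04. Inflammatory genes had 11 of 16 higher and 2 lower (12 and 2 adjusted over the list alone, median log2 2.09, camera adjusted p = 0.011). The chemokine Ccl2 was up (log2 3.81) and lipocalin Lcn2 down (log2 -1.31). Cell cycle genes had 21 of 26 higher and 0 lower (21 and 1 adjusted over the list alone, median log2 0.87, camera adjusted p = 3.6e-07). The mitotic kinase Plk1 was at log2 1.58. Stromal and TGF-beta lists were also higher (medians log2 1.02 and 0.82, camera adjusted p = 0.014 and 0.032). Pdgfrb was at log2 2.44, Inhba at 4.60 and the receptor Tgfbr2 the other way at -1.66. For these 7 lists adjusted p = 0.13 to 0.36 with an estimated correlation. The granzyme gene Gzmc had no counts in the controls and was at least 676-fold higher against a floor of 3 counts over the group. The gut hormone gene Cck was 2140.3-fold (592 to 17678) higher, an interval for counting error only, and its 2 counts in the controls lay in replicate 3. Of genes that fell, Smim41, Rassf4 and the chloride channel Ano1 were at log2 -6.82 (SE 0.32), -5.93 (SE 0.56) and -5.90 (SE 0.37), with Rassf4 at -7.09 without RUNX1 replicate 3. Cardiac muscle genes (sum of 9) reached 136 and 509 CPM in control replicates 1 and 2 and 2224 CPM in RUNX1 replicate 3, against 1.15 to 2.29 CPM in the other 6 libraries. Without those 3 libraries a single control library was left, and the thermogenic median was log2 -1.78. The respiratory chain and stromal lists no longer passed (camera adjusted p = 0.053 and 0.085, with ranges over all settings of 1.9e-07 to 0.053 and 0.0034 to 0.085), nor did the TGF-beta list pass in all fits (camera adjusted p 0.056 without RUNX1 replicate 3). Each of the 39 genes given here that passed the test also passed it with any single library left out.

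Runx2 overexpression lowered most genes of the thermogenic, adipocyte identity and mitochondrial lists (n = 3 per group). None of these lists passed with an estimated correlation (adjusted p = 0.17 to 0.26). Ucp1 fell 592-fold (0.0797 ± 0.0269 against 48.8 ± 12.5 CPM, log2 -9.21, SE 0.33, edgeR QL adjusted p = 2.2e-09) and Cidea 796-fold (log2 -9.64, SE 0.49, and log2 -10.65 without RUNX2 replicate 3). Pparg, a master regulator of fat cells, fell by 0.98 log2 units (SE 0.074) and Plin1 fell by 1.47 log2 units (SE 0.098), while Adipoq did not pass (log2 0.12, SE 0.10). The matrix protease Mmp2 rose to log2 5.97 (SE 0.15) and the interferon-induced Oasl2 to 6.69 (SE 0.16). Of 14661 genes 8928 changed, 4589 higher and 4339 lower, 2513 and 1664 of them at least 2-fold.

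Thermogenic genes had 0 of 20 higher and 13 lower (the same adjusted over the list alone, median log2 -2.15, camera adjusted p = 3.4e-06), or adjusted p = 0.26 with an estimated correlation. Elovl3, Kcnk3, Ebf2 and Prdm16 fell to log2 -3.96 (SE 0.19), -3.35 (SE 0.14), -2.54 (SE 0.12) and -2.40 (SE 0.24), while Ppargc1a did not pass (log2 -0.19, SE 0.24). Adipocyte identity genes had 2 of 25 higher and 18 lower (the same adjusted over the list alone, median log2 -1.01, camera adjusted p = 5.6e-06). The retinol carrier Rbp4 was at log2 -4.19 and the glucose transporter Slc2a4 at -1.84, but carbonic anhydrase Car3 rose (log2 3.52). Lipogenic genes had 1 of 22 higher and 17 lower (the same adjusted over the list alone, median log2 -0.74, camera adjusted p = 3.0e-05). Acacb and Scd1 were at log2 -3.96 and -2.13. Fatty acid oxidation genes had 1 of 24 higher and 21 lower (the same adjusted over the list alone, median log2 -1.49, camera adjusted p = 2.2e-10). Hadhb was at log2 -2.49 and Cpt1a the other way at 1.22. Respiratory chain genes had 0 of 75 higher and 72 lower (the same adjusted over the list alone, median log2 -1.11, camera adjusted p = 1.3e-20). Uqcrfs1 was at log2 -1.86. The TCA cycle and glycolysis lists were lower (medians log2 -1.45 and -2.38, camera adjusted p = 2.1e-10 and 8.0e-11). Idh3a was at log2 -2.06, Bnip3 at -4.19 and Pgk1 at -2.82. For these 6 lists adjusted p = 0.14 to 0.22 with an estimated correlation.

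Matrix genes had 33 of 36 higher and 1 lower (the same adjusted over the list alone, median log2 2.78, camera adjusted p = 2.2e-15) with Runx2. Col1a1, Mmp14 and Postn, a stromal matrix protein, rose to log2 3.30 (SE 0.27), 4.28 (SE 0.17) and 3.01 (SE 0.33). Interferon genes had 22 of 22 higher and 0 lower (the same adjusted over the list alone, median log2 5.76, camera adjusted p = 9.9e-14). Ifi44 was at log2 6.33. Inflammatory genes had 14 of 16 higher and 1 lower (the same adjusted over the list alone, median log2 4.31, camera adjusted p = 2.0e-05). The chemokine Cxcl10 was at log2 5.65. Immediate early genes, which respond to growth signals, had 13 of 14 higher and 0 lower (the same adjusted over the list alone, median log2 2.97, camera adjusted p = 3.6e-09). Fos, Fosb and Egr1 were at log2 5.08 (SE 0.11), 7.04 (SE 0.18) and 4.01 (SE 0.095). Osteochondrogenic genes had 21 of 24 higher and 1 lower (the same adjusted over the list alone, median log2 3.75, camera adjusted p = 3.8e-05). The cartilage factor Sox9 was at log2 2.27 and osteopontin Spp1 at 3.95. Macrophage, stromal, TGF-beta and cell cycle lists were also higher (medians log2 2.97, 2.00, 0.86 and 0.61, camera adjusted p = 0.0033, 0.0011, 0.0020 and 2.9e-05). The lysosomal gene Gpnmb was at log2 6.20, Pdgfrb at 3.18, Inhba at 4.41 and Tyms at 1.22. For these 9 lists adjusted p = 0.14 to 0.22 with an estimated correlation. The collagen gene Col6a5 was at least 2645-fold higher and Depp1, a FOXO-induced gene, at least 998-fold lower against a floor of 3 counts over the group. Without control replicates 1 and 2, which carried the cardiac transcripts, a single control library was left and the thermogenic median was log2 -1.81. Each of the 40 genes given here that passed the test also passed it with any single library left out.

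Compared directly, cultures with Runx2 had lower respiratory chain and adipocyte identity lists (75 of 75 and 23 of 25 genes lower) and higher interferon and immediate early lists (21 of 22 and 11 of 14 higher) than cultures with Runx1 (n = 3 per group). None of these passed with an estimated correlation (adjusted p = 0.077 to 0.28). Fosb, Fos and the nuclear receptor gene Nr4a1, all immediate early, were raised to log2 5.74 (SE 0.16), 5.55 (SE 0.11) and 5.38 (SE 0.19). The carboxylesterase Ces1d and the desaturase Scd3 were lowered to log2 -4.71 (SE 0.39) and -2.94 (SE 0.20). Of 14661 genes 5845 changed, 2767 higher and 3078 lower. Every respiratory chain gene tested was lower (0 of 75 higher and 75 lower, the same adjusted over the list alone, median log2 -0.87, camera adjusted p = 4.6e-27). Fatty acid oxidation, TCA cycle, adipocyte identity, lipogenesis, glycolysis, thermogenic and cell cycle lists were lower too (medians log2 -0.89 to -0.18, camera adjusted p 1.1e-11 to 0.039). Interferon genes had 21 of 22 higher and 0 lower (22 and 0 adjusted over the list alone, median log2 2.50, camera adjusted p = 2.9e-21). Immediate early, inflammatory, matrix, macrophage, stromal and TGF-beta lists were also higher (medians log2 0.28 to 2.66, camera adjusted p 5.1e-13 to 0.020). For all of these adjusted p = 0.077 to 0.53 with an estimated correlation. Against the shared vector controls, 3187 genes rose in both and 2823 fell in both, with 191 opposite. Independent comparisons would share 1294 and 1118. In 10 simulations with no effect 0 were shared, which follows from simulating no effect and does not gauge the overlap. The Pearson correlation of the fold changes across genes was 0.783 and their covariance 1.97, against 0.535 and 0.139 in the simulations. The 3 controls cannot be divided between the comparisons, so part of the overlap may come from them. Each of the 5 genes given here that passed the test also passed it with any single library left out.

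In cultures labelled as Runx1 knockouts few genes changed, nearly all upward, and the matrix and interferon lists were higher (n = 3 per group). Few of their members passed, and neither list did with an estimated correlation (adjusted p = 0.073 to 0.075). Ucp1 was at 50.6 ± 4.79 against 17.6 ± 6.93 CPM, a 2.87-fold difference that did not pass (log2 1.52, SE 0.30, edgeR QL adjusted p = 0.055, 0.012 in a fit of the 2 groups alone and 0.11 to 0.22 with single libraries left out, DESeq2 adjusted p = 1.1e-04). Postn, the gelatinase Mmp2 and the chemokine Cxcl12 rose to log2 1.43 (SE 0.19), 1.71 (SE 0.22) and 1.64 (SE 0.17). Otop1, a proton channel found in brown fat, rose to 1.49 (SE 0.20) and Enpp2, the enzyme autotaxin, fell by 0.74 log2 units (SE 0.10). Of 13551 genes 59 changed, 55 higher and 4 lower. The count was 17, 16 and 23 without Runx1 knockout replicates 1, 2 and 3 and 26, 4 and 28 without control replicates 1, 2 and 3, and 195 in a fit of the 2 groups alone. Thermogenic genes had 2 of 20 higher and 0 lower (3 and 1 adjusted over the list alone, median log2 0.090, camera adjusted p = 0.018), or adjusted p = 0.13 with an estimated correlation. The list was no longer called without control replicate 1 (camera adjusted p = 0.10, 0.0072 to 0.10 over all settings at the preset correlation). Matrix genes had 5 of 35 higher and 0 lower (16 and 0 adjusted over the list alone, median log2 0.51, camera adjusted p = 4.0e-22). Interferon genes had 2 of 20 higher and 0 lower (13 and 0 adjusted over the list alone, median log2 0.89, camera adjusted p = 9.1e-18). Oasl2 and Ifit1 were at log2 2.21 (SE 0.29) and 1.76 (SE 0.25). Stromal, inflammatory and mesothelial lists were higher (medians log2 0.23, 0.32 and 1.13, camera adjusted p = 0.0040, 5.2e-04 and 9.1e-04). The Wnt modulator Sfrp2 was at log2 2.34 and mesothelin Msln at 1.60. Unfolded protein and glycolysis lists were lower with no gene called (medians log2 -0.23 and -0.12, camera adjusted p = 4.8e-05 and 0.0031). Osteochondrogenic, macrophage, cell cycle, adipogenesis inhibitor and TGF-beta lists passed (medians log2 0.084 to 0.60, camera adjusted p 0.0073 to 0.045). Each failed with some libraries left out (camera adjusted p 0.050 to 0.26 without replicates 1, 2 or 3 of either group). For these 12 lists adjusted p = 0.073 to 0.56 with an estimated correlation. Of the 9 genes given here that passed the test, those that no longer did numbered 1 and 1 without Runx1 knockout replicates 1 and 2 and 6 without control replicate 2.

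In cultures labelled as Runx2 knockouts Otop1, Postn and Ifit1 also rose, against the same controls (n = 3 per group). Ucp1 was at 48.2 ± 3.99 against 17.6 ± 6.93 CPM and did not pass (log2 1.45, SE 0.30, edgeR QL adjusted p = 0.090, 0.015 in a fit of the 2 groups alone and 0.18 to 0.36 with single libraries left out, DESeq2 adjusted p = 4.3e-04). Otop1, Postn, Ifit1 and the heart-type fatty acid binding gene Fabp3 were at log2 1.52 (SE 0.20), 1.41 (SE 0.19), 1.56 (SE 0.25) and 1.71 (SE 0.28). The gluconeogenic enzyme Pck1 rose to 1.10 (SE 0.19) and Enpp2 fell by 0.75 log2 units (SE 0.10). Of 13551 genes 25 changed, 24 higher and 1 lower. The count was 4, 0 and 0 without Runx2 knockout replicates 1, 2 and 3 and 0, 0 and 9 without control replicates 1, 2 and 3. In these fits 632 to 881 genes had unadjusted p < 0.05, not far from the share of 0.05 that chance gives among the genes tested. DESeq2 with all libraries called 197 genes and edgeR fitted to the 2 groups alone 105. Thermogenic genes had 2 of 20 higher and 0 lower (4 and 0 adjusted over the list alone, median log2 0.27, camera adjusted p = 1.7e-06). The list kept adjusted p = 0.049 with an estimated correlation and 8.2e-08 to 2.6e-04 over all settings at the preset correlation. Interferon genes had 1 of 20 higher and 0 lower (13 and 0 adjusted over the list alone, median log2 0.86, camera adjusted p = 1.1e-16), or adjusted p = 0.049 with an estimated correlation. Matrix, inflammatory, futile cycle and mesothelial lists were higher (medians log2 0.25 to 0.76, camera adjusted p 1.0e-05 to 0.0047). Msln was at log2 1.51. Unfolded protein and glycolysis lists were lower (medians log2 -0.17 and -0.16, camera adjusted p = 0.0019 and 5.1e-05). Adipocyte identity and fatty acid oxidation lists passed (medians log2 0.14 and 0.11, camera adjusted p = 0.040 and 0.045) but each failed with some libraries left out (camera adjusted p 0.063 to 0.52 without Runx2 knockout replicates 1 or 2 or control replicates 1, 2 or 3). For these 8 lists adjusted p = 0.067 to 0.42 with an estimated correlation. Of the 7 genes given here that passed the test, those that no longer did numbered 6, 7 and 7 without Runx2 knockout replicates 1, 2 and 3 and 7, 7 and 4 without control replicates 1, 2 and 3.

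In the double knockout cultures Ucp1 rose and the interferon, cell cycle and matrix lists were higher (n = 3 per group), the matrix list not with an estimated correlation (adjusted p = 0.31). Ucp1 rose 5.39-fold (95.1 ± 31.9 against 17.6 ± 6.93 CPM, log2 2.43, SE 0.31, edgeR QL adjusted p = 3.7e-04), and Otop1 and Fabp3 rose to log2 3.36 (SE 0.21) and 3.32 (SE 0.28). The matrix genes Postn, Col3a1 and Col1a1 rose to log2 2.74 (SE 0.20), 2.32 (SE 0.24) and 1.24 (SE 0.25). The progenitor genes Sfrp2, Dlk1 and Ly6a rose to log2 3.59 (SE 0.29), 3.55 (SE 0.34) and 3.21 (SE 0.32). The flavin monooxygenase Fmo1, Mycl and Enpp2 fell to log2 -2.11 (SE 0.20), -1.97 (SE 0.21) and -1.77 (SE 0.11). Of 13551 genes 2070 changed, 1120 higher and 950 lower, 580 and 141 of them at least 2-fold. The count was 3584 without double knockout replicate 1 and 1050 and 1246 without control replicates 2 and 3, and 379 in a fit of the 2 groups alone. Thermogenic genes had 6 of 20 higher and 2 lower (8 and 3 adjusted over the list alone, median log2 0.44, camera adjusted p = 0.086) and did not pass as a list. Camera adjusted p was 0.042 without double knockout replicate 1 and 0.042 without control replicate 2 (0.042 to 0.20 over all settings at the preset correlation). Ppargc1a (log2 0.87, 2 of 3 libraries above all controls) and Lep (log2 1.87) rose, and Pparg, Adipoq and Plin1 did not pass (log2 0.23, -0.13 and -0.16). Interferon genes had 17 of 20 higher and 0 lower (19 and 0 adjusted over the list alone, median log2 1.86, camera adjusted p = 5.2e-15). Ifit1 was at log2 3.00. Inflammatory genes had 9 of 13 higher and 0 lower (10 and 0 adjusted over the list alone, median log2 1.47, camera adjusted p = 6.6e-06). Ccl2 and Lcn2 were at log2 4.04 and 1.73. Cell cycle genes had 17 of 26 higher and 0 lower (18 and 0 adjusted over the list alone, median log2 0.69, camera adjusted p = 8.0e-10). Bub1 was at log2 1.03. These 3 lists had adjusted p = 0.046 with an estimated correlation. Matrix genes had 15 of 35 higher and 0 lower (20 and 0 adjusted over the list alone, median log2 0.68, camera adjusted p = 8.9e-09). Stromal and mesothelial lists were higher (medians log2 0.59 and 2.26, camera adjusted p = 0.0084 and 0.014). Msln was at log2 2.26. Futile cycle, unfolded protein and respiratory chain lists passed (medians log2 0.46, -0.12 and 0.48, camera adjusted p = 0.042, 0.042 and 7.4e-04) but each failed with some libraries left out (camera adjusted p 0.053 to 0.33 without double knockout replicates 1, 2 or 3 or control replicate 1). The respiratory chain median turned to log2 -0.045 without double knockout replicate 1. For these 6 lists adjusted p = 0.082 to 0.69 with an estimated correlation. Of the 19 genes given here that passed the test, those that no longer did numbered 1 and 1 without double knockout replicates 2 and 3 and 1 and 1 without control replicates 1 and 3. Given genes that passed only then numbered 1 without double knockout replicate 1.

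**Figure D2:**
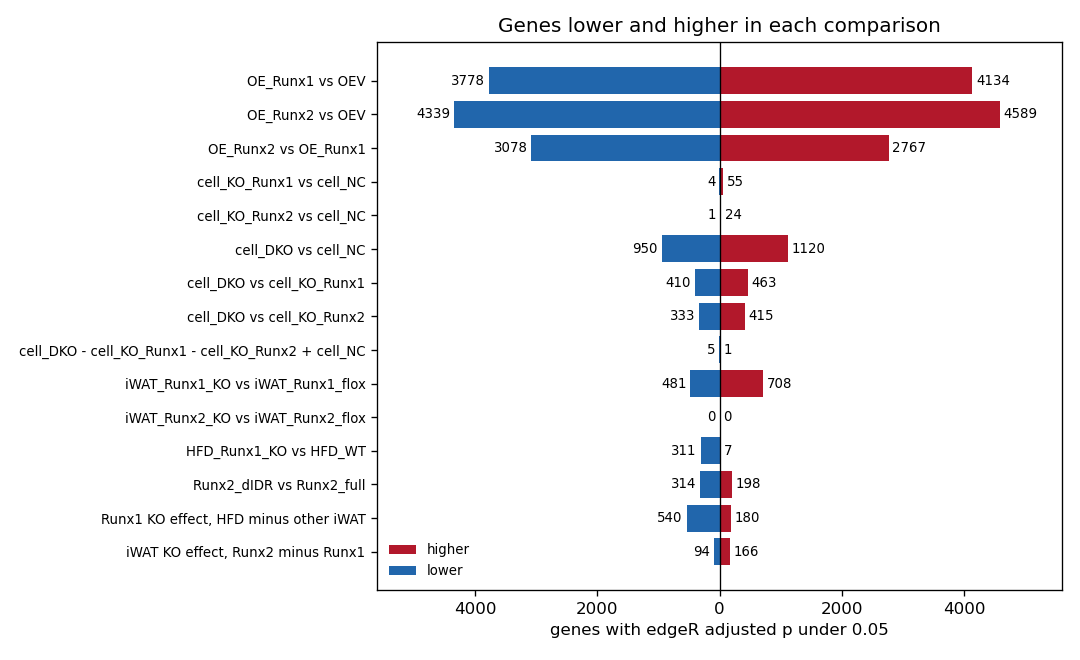
Number of genes higher and lower in each comparison at edgeR QL adjusted p < 0.05.

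Against the single knockouts, the interferon, inflammatory and cell cycle lists were higher in the double knockout in both cases (n = 3 per group). With an estimated correlation, of these only the inflammatory and cell cycle lists against the Runx2 knockout still passed. Ly6a was at log2 2.06 (SE 0.30) against the Runx1 knockout and 2.01 (SE 0.29) against the Runx2 knockout, and S100a4, a calcium-binding gene of fibroblasts, at 1.88 (SE 0.34) and 2.17 (SE 0.35). Fmo1 was at log2 -1.60 and -1.83, and the PI3K inhibitor Pik3ip1 at -1.51 and -1.54. Against the Runx1 knockout 873 of 13551 genes changed (463 higher, 410 lower), with 1779 and 1952 without double knockout replicates 1 and 3 and 191, 176 and 268 without Runx1 knockout replicates 1, 2 and 3. Against the Runx2 knockout 748 changed (415 higher, 333 lower), with 1768 and 1214 without double knockout replicates 1 and 3 and 264, 224 and 205 without Runx2 knockout replicates 1, 2 and 3. Fits of the 2 groups alone gave 7 and 31 genes. The thermogenic list passed against neither (medians log2 0.27 and 0.069, camera adjusted p 0.39 and 0.88). Against the Runx1 knockout, interferon genes had 8 of 20 higher and 0 lower (14 and 0 adjusted over the list alone, median log2 0.86, camera adjusted p = 7.2e-09). Inflammatory, cell cycle, stromal and respiratory chain lists were higher (medians log2 0.51 to 0.97, camera adjusted p 9.8e-10 to 0.036), all at adjusted p = 0.11 to 0.97 with an estimated correlation. Against the Runx2 knockout, cell cycle, inflammatory and stromal lists were higher (medians log2 0.37 to 1.08, camera adjusted p 1.2e-10 to 7.8e-04), all 3 still at adjusted p = 0.046 with an estimated correlation. Interferon, matrix, respiratory chain, osteochondrogenic and mesothelial lists were higher too and adipocyte identity lower (median log2 -0.12), at camera adjusted p 2.1e-10 to 0.025 and adjusted p = 0.10 to 0.82 with an estimated correlation. Against the Runx1 knockout, S100a4 no longer passed without Runx1 knockout replicates 1 or 2 (highest edgeR QL adjusted p 0.059). Against the Runx2 knockout, each of the 4 genes given here also passed with any single library of the 2 groups left out.

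Few genes departed from the sum of the 2 single knockout effects. The stress gene Ddit4 was above the sum in the double knockout (log2 1.11, SE 0.15), and Rnf144b, the immediate early gene Egr1, Pik3ip1 and the lipase inhibitor Angptl4 were below it at log2 -1.55 (SE 0.16), -1.50 (SE 0.20), -1.37 (SE 0.16) and -1.23 (SE 0.16). Of 13551 genes 6 were called (1 above and 5 below, 1495 at unadjusted p < 0.05), and DESeq2 gave 207. The count was 218 and 1 without double knockout replicates 1 and 2, 2, 0 and 1 without Runx1 knockout replicates 1, 2 and 3, 2, 3 and 2 without Runx2 knockout replicates 1, 2 and 3 and 3, 1 and 1 without control replicates 1, 2 and 3. Cell cycle, respiratory chain and glycolysis lists were above the sum and adipocyte identity below it (medians log2 0.50, 0.52, 0.21 and -0.18, camera adjusted p 1.5e-08 to 0.025), all at adjusted p = 0.16 to 0.83 with an estimated correlation. Ucp1 and the thermogenic list were not called (median log2 -0.14, camera adjusted p 0.25). Genes called in both single knockouts were 15 higher and 1 lower, against 0.0974 and 0.000295 expected of independent comparisons, with Pearson correlation 0.709 and covariance 0.126 against 0.512 and 0.0615 in 10 simulations without effect. The Runx1 and double knockouts shared 51 higher and 4 lower genes (4.55 and 0.280 independent, covariance 0.186 against 0.0613 simulated), and the Runx2 and double knockouts 21 and 1 (1.98 and 0.0701 independent, covariance 0.183 against 0.0606 simulated). The simulations shared 0 genes, which follows from simulating no effect. Since all comparisons use the same 3 controls, part of the overlap may come from them. Of the 5 genes given here that passed the test, those that no longer did numbered 4 without double knockout replicate 2, 3, 5 and 4 without Runx1 knockout replicates 1, 2 and 3, 3, 2 and 3 without Runx2 knockout replicates 1, 2 and 3 and 2, 4 and 4 without control replicates 1, 2 and 3.

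In iWAT of Runx1 knockouts, the thermogenic, lipogenic and mitochondrial lists were higher and the matrix and TGF-beta lists lower than in floxed controls (n = 3 per group). Most members did not pass when adjusted over all genes, and none of these lists passed with an estimated correlation (adjusted p = 0.33 to 0.62). Ucp1 rose 7.35-fold (113 ± 52.4 against 15.4 ± 6.13 CPM, log2 2.88, SE 0.53, edgeR QL adjusted p = 0.044). Its adjusted p was 0.062 to 0.14 in edgeR QL without Runx1 knockout replicates 1 or 3 or any floxed replicate. Over the alternatives that kept more than a single library per group it ran from 2.0e-06 (DESeq2) to 0.17 (edgeR QL with the replicate block). Fatty acid synthase Fasn rose to log2 1.24 (SE 0.19), and Hcar1, the lactate receptor of fat cells, to 3.44 (SE 0.31). Ppargc1a fell by 2.10 log2 units (SE 0.40) and the matrix protein gene Thbs1 fell by 1.98 log2 units (SE 0.19). Of 15896 genes 1189 changed, 708 higher and 481 lower, 214 and 155 at least 2-fold. The count was 440, 99 and 300 without Runx1 knockout replicates 1, 2 and 3 and 676 without Runx1-floxed replicate 3. Thermogenic genes had 6 of 21 higher and 1 lower (14 and 1 adjusted over the list alone, median log2 1.18, camera adjusted p = 1.1e-05), or adjusted p = 0.62 with an estimated correlation. The beta-3 adrenergic receptor Adrb3 and Elovl3 rose to log2 2.32 (SE 0.32) and 3.21 (SE 0.75), with Elovl3 at 4.34 without Runx1-floxed replicate 2, while Cidea (log2 2.17, SE 0.51) and Dio2 (log2 0.22, SE 0.27) did not pass. The insulin substrate gene Irs3 rose to log2 3.84 and the heat shock gene Hspa1a, a near copy of Hspa1b, to 3.34, while Irf4 and the carrier gene Slc25a25 fell to log2 -3.87 and -3.86 (-2.98 and -3.20 without Runx1-floxed replicate 2). Adipoq, Fabp4 and Plin1 did not pass (log2 0.0021, 0.18 and 0.15).

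Respiratory chain genes had 23 of 75 higher and 0 lower (50 and 0 adjusted over the list alone, median log2 0.47, camera adjusted p = 2.0e-21) in these mice. Uqcr11 was at log2 1.20. Lipogenic genes had 10 of 22 higher and 0 lower (13 and 0 adjusted over the list alone, median log2 0.53, camera adjusted p = 2.7e-07). Mid1ip1 and Gpam were at log2 1.45 and 1.28. Fatty acid oxidation genes had 7 of 23 higher and 0 lower (15 and 1 adjusted over the list alone, median log2 0.50, camera adjusted p = 2.0e-06). The TCA cycle list was higher (median log2 0.46, camera adjusted p = 5.5e-06). Acadvl was at log2 0.86. Matrix genes had 0 of 36 higher and 4 lower (0 and 11 adjusted over the list alone, median log2 -0.51, camera adjusted p = 4.9e-08). Ccn2 was at log2 -1.24. TGF-beta genes had 0 of 20 higher and 4 lower (0 and 8 adjusted over the list alone, median log2 -0.42, camera adjusted p = 8.1e-04). The inhibin chain Inhbb was at log2 -1.70. Endothelial and cell cycle lists were lower (medians log2 -0.43 and -0.60, camera adjusted p = 1.0e-04 and 9.9e-05). The VEGF receptor Kdr was at log2 -0.99. White-selective and skeletal muscle lists (medians log2 0.17 and 1.71) passed as higher and macrophage, MHC class II and immediate early lists (medians log2 -0.23, -0.37 and -1.21) as lower. These were at camera adjusted p 0.013 to 0.044, but each failed with some libraries left out (camera adjusted p 0.052 to 0.51 without Runx1 knockout replicates 1, 2 or 3 or Runx1-floxed replicates 1, 2 or 3). For these 13 lists adjusted p = 0.33 to 0.62 with an estimated correlation. Skeletal muscle genes summed to 9688 CPM in Runx1-floxed replicate 2 and 21880 and 11042 CPM in Runx1 knockout replicates 2 and 3, against 58.0 to 319 CPM in the others. Without those 3 libraries, which left a single Runx1 knockout library, the thermogenic median was log2 1.39 and the endothelial list no longer passed. Of the 18 genes given here that passed the test, those that no longer did numbered 6, 8 and 6 without Runx1 knockout replicates 1, 2 and 3 and 4, 2 and 3 without Runx1-floxed replicates 1, 2 and 3. Given genes that passed only then numbered 2 and 1 without Runx1-floxed replicates 1 and 2.

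In iWAT of Runx2 knockouts the thermogenic list was higher although no single gene passed (n = 3 per group), but not with an estimated correlation (adjusted p = 0.67). Ucp1 was at 384 ± 283 against 9.39 ± 8.83 CPM (log2 5.36, SE 1.03, edgeR QL adjusted p = 0.22, 3 of 3 libraries above all controls, 1.0e-08 to 0.56 and log2 4.84 to 6.48 over all alternatives, highest without Runx2-floxed replicate 3). Elovl3 was at log2 6.76 (SE 0.92), with only 6 counts over the control group, and the thyroid hormone deiodinase Dio2 at 3.18 (SE 0.50). Cidea and Ppargc1a were at log2 2.89 (SE 0.53) and 1.76 (SE 0.29). Of 15574 genes 0 passed with edgeR (lowest adjusted p 0.12), 3206 had unadjusted p < 0.05 (1469 higher, 1737 lower), and DESeq2 called 1039. The count was 5 without Runx2 knockout replicate 1 and 6354 without Runx2-floxed replicate 3. Thermogenic genes had 0 of 21 higher and 0 lower (13 and 0 adjusted over the list alone, median log2 1.60, camera adjusted p = 5.3e-09). Fatty acid oxidation genes had 0 of 23 higher and 0 lower (20 and 0 adjusted over the list alone, median log2 1.08, camera adjusted p = 2.3e-12). TCA cycle genes had 0 of 16 higher and 0 lower (16 and 0 adjusted over the list alone, median log2 1.02, camera adjusted p = 2.2e-11). Adipocyte identity, respiratory chain, lipogenesis, white-selective and unfolded protein lists were also higher (medians log2 0.42 to 0.90, camera adjusted p 1.2e-12 to 0.0064). Pparg, Adipoq and Plin1 were at log2 0.73 (SE 0.32), 0.84 (SE 0.43) and 1.18 (SE 0.43). T cell genes had 0 of 14 higher and 0 lower (0 and 10 adjusted over the list alone, median log2 -1.17, camera adjusted p = 9.4e-07). The cell cycle list was lower as well (median log2 -0.67, camera adjusted p = 3.7e-04). Interferon, endothelial and matrix lists (medians log2 0.47, 0.44 and 0.17) passed as higher and B cell, MHC class II, macrophage and neutrophil lists (medians log2 -1.39, -1.15, -0.27 and -0.70) as lower. These were at camera adjusted p 6.3e-04 to 0.035. Each failed with some libraries left out (camera adjusted p 0.056 to 0.43 without replicates 1, 2 or 3 of either group). For all of these adjusted p = 0.67 to 0.76 with an estimated correlation. Skeletal muscle genes summed to 10830 CPM in Runx2-floxed replicate 3 (84.1 to 654 CPM in the others), and B cell genes to 2680, 2955 and 447 CPM in the floxed libraries and 370 to 830 CPM in the knockouts.

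In the iWAT labelled HFD, most genes of the B and T cell lists were lower in Runx1 knockouts and no thermogenic gene passed (n = 3 per group). With an estimated correlation the B cell, T cell and MHC class II lists did not pass (adjusted p = 0.20). The B cell receptor gene Cd79a fell 106-fold (0.755 ± 0.146 against 79.9 ± 23.4 CPM, log2 -6.73, SE 0.33, edgeR QL adjusted p = 1.9e-06), and the B cell genes Ms4a1 and Fcer2a fell to log2 -8.15 (SE 0.58) and -8.69 (SE 0.71), with Ms4a1 at -8.94 without HFD knockout replicate 1. Runx3, a family member expressed in T cells, fell by 3.35 log2 units (SE 0.67). Ucp1 was at 0.776 ± 0.433 against 27.0 ± 44.8 CPM and did not pass (log2 -5.14, SE 2.19, edgeR QL adjusted p = 0.65, 1 of 3 libraries below all controls). HFD wild-type replicate 2 had 79.8 CPM, and without it Ucp1 was at log2 -0.55. Of 15058 genes 318 changed, 7 higher and 311 lower, with 120 without HFD knockout replicate 1 and 197 and 176 without HFD wild-type replicates 2 and 3. B cell genes had 0 of 11 higher and 11 lower (the same adjusted over the list alone, median log2 -6.35, camera adjusted p = 6.0e-31). T cell genes had 0 of 14 higher and 11 lower (0 and 12 adjusted over the list alone, median log2 -3.19, camera adjusted p = 4.9e-23). MHC class II genes had 0 of 7 higher and 2 lower (0 and 6 adjusted over the list alone, median log2 -0.70, camera adjusted p = 4.3e-08). H2-DMa was at log2 -1.13. The thermogenic list was lower (median log2 -0.52, camera adjusted p 0.0032, 0 genes called and 0 adjusted over the list alone). It did not pass without HFD wild-type replicate 2 (camera adjusted p = 0.43). Over all settings at the preset correlation camera adjusted p ran from 3.9e-05 to 0.43. The lowest came with the B cell score as covariate, where the list was higher instead. The TCA cycle list was lower and endothelial and Schwann cell lists higher (medians log2 -0.34, 0.38 and 0.63, camera adjusted p = 1.5e-04, 1.1e-05 and 2.1e-05). Beige marker, fatty acid oxidation, respiratory chain, cell cycle and neutrophil lists (medians log2 -0.57 to -0.13) passed as lower and interferon and macrophage lists (medians log2 0.66 and 0.37) as higher. These were at camera adjusted p 2.9e-05 to 0.040, but each failed with some libraries left out (camera adjusted p 0.053 to 0.93 without HFD knockout replicates 1, 2 or 3 or HFD wild-type replicates 1 or 2). For all of these adjusted p = 0.20 to 0.75 with an estimated correlation. The only beige markers called were Cd40 and Tnfrsf9 (log2 -1.94 and -2.19). Whether adipocytes or lymphocytes expressed them was not tested. Of the few genes that rose, Vsig2 was at log2 1.32 (SE 0.23), and Adipoq, Pparg and Lep did not pass (log2 -0.18, 0.24 and -0.035). Of the 6 genes given here that passed the test, Cd40 and Tnfrsf9 left out, those that no longer did numbered 3, 1 and 1 without HFD knockout replicates 1, 2 and 3 and 3 and 2 without HFD wild-type replicates 2 and 3.

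**Figure D3:**
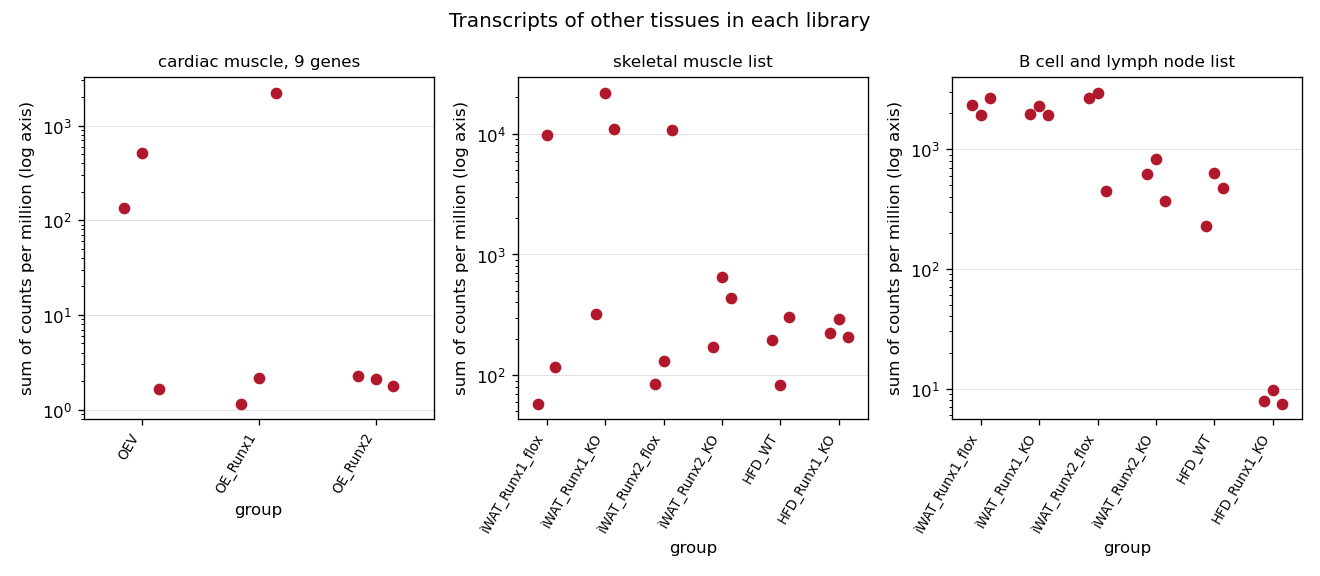
Summed CPM of cardiac muscle genes in the overexpression libraries and of skeletal muscle and B cell genes in the fat libraries, on log axes. Single libraries carried most of the muscle transcripts.

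The Runx1 knockout effect in iWAT differed between the HFD table and the other table, where HFD and table cannot be separated. The stress-responsive genes Apold1 and Sik1 and the carrier gene Slc25a25 were among the most positive differences (HFD minus other), at log2 3.85 (SE 0.58), 3.57 (SE 0.54) and 3.81 (SE 0.58), with Slc25a25 at 3.17 without Runx1-floxed replicate 2. Serpina10, the lymph node vessel gene Glycam1 and the desmosome gene Dsg2 were among the most negative, all with no counts in the HFD knockouts, so no fold is given. Of 16361 genes 720 differed, 180 higher and 540 lower under HFD. The count was 390 without HFD knockout replicate 1, 347 without HFD wild-type replicate 2, 469, 308 and 424 without Runx1 knockout replicates 1, 2 and 3 and 407 and 463 without Runx1-floxed replicates 2 and 3. Thermogenic genes had 0 of 21 higher and 3 lower (1 and 13 adjusted over the list alone, median log2 -1.77, camera adjusted p = 1.2e-05). Beige marker, white-selective, lipogenesis, fatty acid oxidation, TCA cycle, respiratory chain, B cell, T cell and MHC class II lists were likewise lower (camera adjusted p 1.9e-16 to 0.024). Matrix, TGF-beta, macrophage, endothelial, Schwann cell and immediate early lists were higher (medians log2 0.33 to 0.87, camera adjusted p 1.1e-08 to 0.014). For all of these adjusted p = 0.34 to 0.63 with an estimated correlation. Each of the 6 genes given here that passed the test also passed it with any single library left out.

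Between the Runx2 and Runx1 knockouts in iWAT, Irf4, Slc25a25 and Ppargc1a differed upward and Hcar1, Irs3 and Adrb3 downward. The differences were log2 5.53 (SE 0.81), 4.65 (SE 0.73) and 3.89 (SE 0.49) for the former and -5.24 (SE 0.53), -3.40 (SE 0.62) and -2.76 (SE 0.43) for the latter. Without Runx2-floxed replicate 3 Irf4, Slc25a25 and Irs3 were at log2 6.27, 5.28 and -2.65, and without Runx1-floxed replicate 2 Irf4 and Slc25a25 at 4.62 and 3.96. Of 16416 genes 260 differed, 166 higher and 94 lower. The count was 47, 159 and 3 without Runx2 knockout replicates 1, 2 and 3, 74, 49 and 4173 without Runx2-floxed replicates 1, 2 and 3, 145, 4 and 81 without Runx1 knockout replicates 1, 2 and 3 and 110 and 42 without Runx1-floxed replicates 1 and 2. Thermogenic genes had 2 of 22 higher and 1 lower (the same adjusted over the list alone, median log2 0.84, camera adjusted p = 0.045). Adipocyte identity, fatty acid oxidation, TCA cycle, matrix, TGF-beta, endothelial, smooth muscle and unfolded protein lists were higher too (medians log2 0.43 to 0.90, camera adjusted p 1.9e-07 to 0.049). T cell and skeletal muscle lists were lower (medians log2 -1.19 and -5.39, camera adjusted p 7.7e-04 to 0.042). For all of these adjusted p = 0.85 with an estimated correlation. Of the 6 genes given here that passed the test, those that no longer did numbered 1 and 4 without Runx1 knockout replicates 1 and 2, 1 and 1 without Runx1-floxed replicates 1 and 2, 1 and 5 without Runx2 knockout replicates 1 and 3 and 1 without Runx2-floxed replicate 2.

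Cultures with Runx2 lacking the IDR had a lower matrix list and a higher glycolysis list than those with full-length Runx2 (n = 2 per group), though not with an estimated correlation (adjusted p = 0.55). As Runx2 counts were also lower there, effects of the missing part and of a lower dose were not separated. The matricellular gene Ccn5, the imprinted gene Mest and Tnc fell to log2 -3.28 (SE 0.20), -2.55 (SE 0.15) and -2.33 (SE 0.16), and the collagenase Mmp13, a known RUNX2 target, fell to 4 counts over the group from 86 (log2 -4.30, SE 0.76, and -3.35 without IDR-deleted replicate 1, which had 0). Ucp1 rose 2.27-fold (12.4 ± 1.63 against 5.49 ± 2.62 CPM, log2 1.18, SE 0.25, edgeR QL adjusted p = 0.020, but DESeq2 adjusted p = 0.25). It was at log2 1.77 and 0.76 without full-length replicates 1 and 2. The adenylate kinase Ak4 and the prolyl hydroxylases P4ha2 and P4ha1, all hypoxia-induced, rose to log2 1.26 (SE 0.18), 1.00 (SE 0.14) and 0.83 (SE 0.096). Of 13110 genes 512 changed, 198 higher and 314 lower, 21 and 47 at least 2-fold. The count was 269 and 1214 without IDR-deleted replicates 1 and 2 and 242 without full-length replicate 2, where the lone remaining library of a group was assumed to vary like the others. Glycolysis genes had 9 of 17 higher and 1 lower (13 and 1 adjusted over the list alone, median log2 0.53, camera adjusted p = 3.9e-22). Aldoa and Eno1 were at log2 0.56 and 0.53 and Pfkfb3 down at -0.51. Matrix genes had 0 of 34 higher and 12 lower (2 and 18 adjusted over the list alone, median log2 -0.22, camera adjusted p = 6.8e-09). Thbs1 and Thbs2 were at log2 -0.66 and -0.72. Lipogenic genes had 5 of 22 higher and 0 lower (11 and 2 adjusted over the list alone, median log2 0.16, camera adjusted p = 3.5e-05). Fasn and Scd2 were at log2 0.48 and 0.52. The respiratory chain list was higher (median log2 0.14, camera adjusted p = 2.1e-14). Osteochondrogenic, stromal and immediate early lists (medians log2 -0.37 to -0.12) passed as lower, with Spp1 at log2 -0.76 and Egr1 at -0.84. Adipocyte identity, fatty acid oxidation, TCA cycle, unfolded protein, cholesterol and smooth muscle lists (medians log2 0.078 to 0.26) passed as higher, with Rbp4 at log2 0.67. These 9 lists were at camera adjusted p 0.010 to 0.050, but each failed with some library left out. For all 13 lists adjusted p = 0.55 to 0.58 with an estimated correlation. Thermogenic genes had 3 of 19 higher and 1 lower (5 and 1 adjusted over the list alone, median log2 -0.011, mean 0.11, camera adjusted p = 0.079) and did not pass as a list. Camera adjusted p was 0.0093 without IDR-deleted replicate 1 and 0.027 without full-length replicate 1 (0.0093 to 0.36 over all settings at the preset correlation). Every fit with a library left out had a single library in a group, so a pass there is no sign of a firm call.

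**Figure D4:**
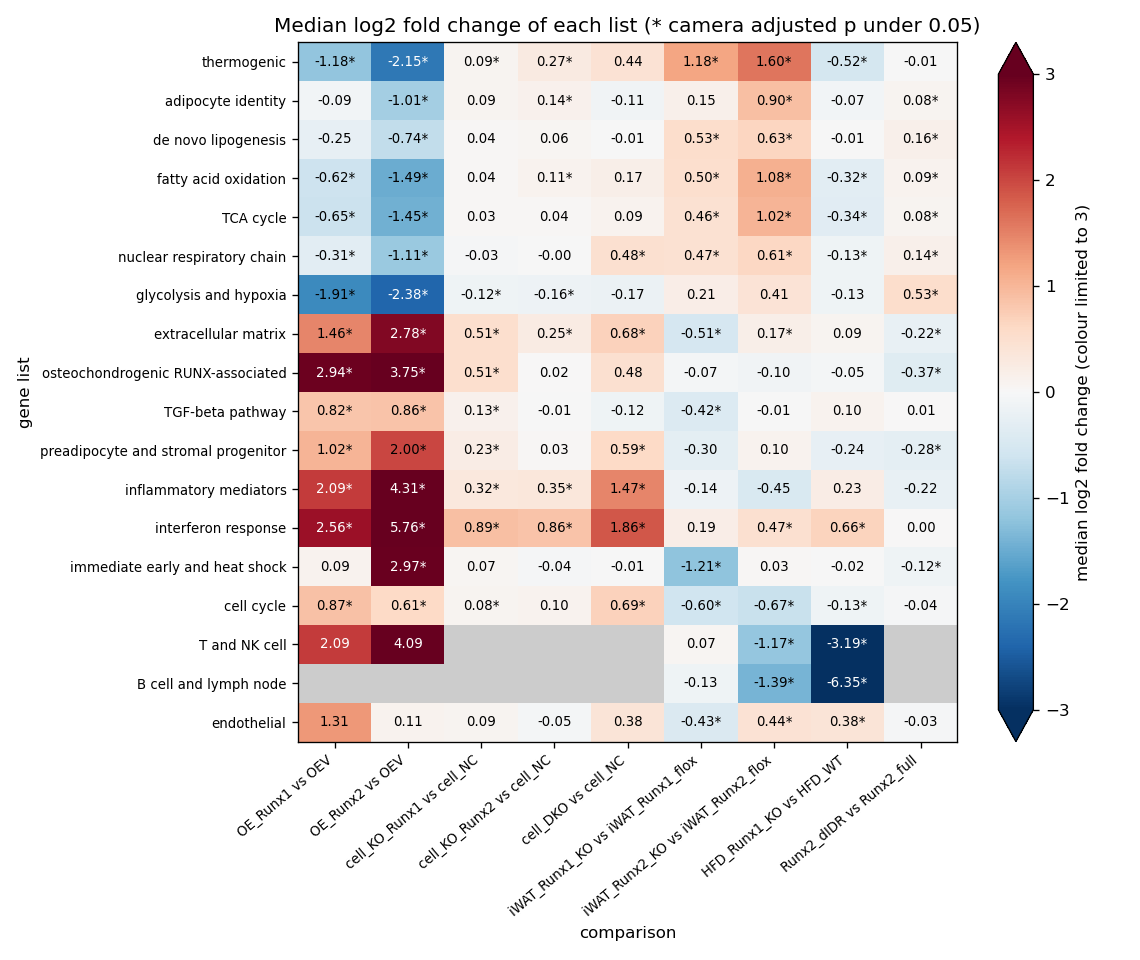
Median log2 fold change of 18 gene lists in 9 comparisons, with colour limited to 3 and asterisks at camera adjusted p < 0.05. Grey marks lists that could not be tested.

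Genes changed at least 2-fold in a table were then followed as sets in other tables. The 1369 genes raised by Runx1 and measured in both were higher, not lower, in the Runx1 knockout cultures (median log2 0.22, 33 higher and 1 lower, camera adjusted p = 1.8e-15, adjusted p = 5.8e-04 with an estimated correlation). In turn the 43 genes raised in that knockout, Oasl2 and Mmp2 among them, were higher under Runx1 overexpression (25 higher, 6 lower, camera adjusted p = 2.3e-04, adjusted p = 0.64 with an estimated correlation). The 1846 genes raised by Runx2 were higher in the Runx2 knockout cultures (median log2 0.12, camera adjusted p = 5.1e-06, adjusted p = 0.18 with an estimated correlation). Of 45 genes lower with the shortened form, among them Tnc, Ccn5 and Mest, 37 rose and 2 fell under Runx2 overexpression (median log2 3.42, camera adjusted p = 1.7e-10, adjusted p = 0.12 with an estimated correlation). Genes raised by Runx2 were lower with the shortened form (1756 genes, median log2 -0.070, 13 higher and 128 lower, camera adjusted p = 0.0015, adjusted p = 0.45 with an estimated correlation). Genes lowered by Runx2 were higher there (1570 genes, median log2 0.074, 106 higher and 36 lower, camera adjusted p = 5.5e-06, adjusted p = 0.25 with an estimated correlation). Genes raised in Runx1 knockout iWAT were higher in Runx2 knockout iWAT (212 genes, median log2 0.22, camera adjusted p = 7.4e-04), and genes lowered under HFD, such as Cd79a, were lower in the other Runx1 table (310 genes, median log2 -0.16, camera adjusted p = 0.0082), at adjusted p = 0.64 and 0.73 with an estimated correlation. Across genes, fold changes correlated at Pearson 0.207 between Runx1 overexpression and knockout cultures, 0.122 between those for Runx2 and -0.191 between Runx2 overexpression and the shortened form. Between the knockout cultures and iWAT they correlated at -0.0414 (Runx1) and 0.0236 (Runx2), and between the Runx1 iWAT table and the HFD and Runx2 iWAT tables at 0.0157 and 0.00154.

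The deposited lists of changed genes for the HFD and IDR tables largely matched the genes that passed here. The HFD list had 403 genes (18 higher, 385 lower), with Cd79a at log2 -6.73 and Cd79b at -5.68. Of these 384 were tested here, and 309 passed with edgeR and 383 with DESeq2, all 384 with the same sign. The IDR list had 341 genes (124 higher, 217 lower), with Ccn5 at log2 -3.29 and Mest at -2.55. All were tested, and 339 passed with edgeR and 338 with DESeq2, all with the same sign.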

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

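Chosen after the results were seen were the tests of library depth, of dilution by other tissue, of fewer adipocytes and of single libraries in the double knockout comparison, the 25 lymph node genes, and the correlation with B cell genes by table and with libraries left out; the others were set before.

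Differences between groups were tested directly in 3 cases. The double knockout departed from the sum of the single knockouts at 6 genes, Rnf144b and Ddit4 among them. Of 100 splits of the 12 libraries 3 gave as many, the real one included. The highest other split gave 413, but its contrast set the intact double knockouts against the intact controls. Such splits test for any difference between the groups, so they cannot decide whether the effects add. The Runx1 knockout effect in iWAT differed between the HFD table and the other at 720 genes, more than in any other of 100 splits. The highest other split gave 486 and kept the HFD groups intact. These splits too test for any knockout effect, not for a difference between the effects. The thermogenic median of the difference was log2 -1.77 (camera adjusted p = 1.2e-05, adjusted p = 0.37 with an estimated correlation). The Runx2 and Runx1 knockout effects in iWAT differed at 260 genes, with Irf4 higher and Hcar1 lower, and 4 of 100 splits gave as many. The highest gave 1176 and kept the Runx1 groups intact, so these splits cannot decide on the difference either. The thermogenic difference was log2 0.84 (camera adjusted p = 0.045, adjusted p = 0.85 with an estimated correlation). Table, diet and genotype cannot be separated in the last 2.

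For comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. The real split gave the most genes, 1 of 10, in both overexpression comparisons (7912 and 8928), the contrast between them (5845), the 3 knockout cultures (59, 25 and 2070), and the double against the single knockouts (873 and 748), where the highest other split gave 0. It also did in Runx1 knockout iWAT (1189, highest other 145) and under HFD (318, highest other 1). In Runx2 knockout iWAT all 10 splits gave as many as the real one, since that gave 0, with 3206 genes at unadjusted p < 0.05 and 1039 called by DESeq2.

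Lymphocyte genes such as Cd79a and Ms4a1 were far lower in HFD knockout iWAT than in its controls. Library depth does not account for this, at a ratio of 1.04 between knockout and control totals. Over the 12 libraries of the other 2 iWAT tables, the genes lowered under HFD had a median within-group correlation with B cell genes of 0.891 (quartiles 0.808 and 0.952), against -0.0536 for other genes. The median was 0.550 in the Runx1 table alone and 0.968 in the Runx2 table, and 0.601 to 0.918 with single libraries left out, lowest without Runx2-floxed replicate 3 (quartiles 0.397 and 0.772). Lymphocyte genes go together in either case, so this cannot tell lymph node tissue in the control dissections from a loss of lymphocytes in the knockout fat. Of 25 tested genes known from lymph node vessels, stroma or sinuses, picked outside the rule for names, 5 were called lower under HFD and 0 higher. These were Glycam1 and Chst4, with no counts in the knockouts, and Cxcl13, Marco and Cd209b (log2 -4.79, -2.74 and -2.47). Chst4 no longer passed without HFD knockout replicate 1. The other 20 did not pass, and fat expresses several of them too. Called or not, 17 of the 25 were lower. Lymph node tissue may be a source of part of these transcripts, and a loss of lymphocytes with their vessels and stroma stays open too.

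The thermogenic list was higher in Runx2 knockout iWAT (camera adjusted p = 5.3e-09, but adjusted p = 0.67 with an estimated correlation), although edgeR called 0 genes. Runx2-floxed replicate 3 stands apart: without it 6354 genes passed, and its skeletal muscle sum was 10830 CPM. Its B cell sum of 447 CPM and adipocyte score of 10.39 were near those of the knockouts (370 to 830 CPM and 10.46 to 10.56), against 2680 and 2955 CPM and 8.84 and 9.16 in the other controls. Without it the groups thus also differ in lymphoid and adipocyte content. The thermogenic score rose 0.885 log2 units more than the score of adipocyte genes (0.42 to 1.35 with its SE of 0.46), so dilution of adipocyte RNA by other tissue in the controls may account for part of the rise and could not be told apart from a higher expression per adipocyte. An effect of the genotype stays open, as untested.

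Matrix and interferon genes such as Col1a1 and Ifit1 were higher both in cultures with more Runx1 or Runx2 and in double knockouts. With an estimated correlation neither list passed there (adjusted p 0.13 to 0.32) except the interferon list in the double knockout (adjusted p 0.046). A single library does not account for the double knockout part at the preset correlation: with each of the 6 libraries left out in turn, the highest camera adjusted p of both lists was 4.8e-05, without double knockout replicate 3. The score of adipocyte genes fell by 0.0697 log2 units in the double knockout, about 1 SE (0.0657). The scores of the double knockout libraries (8.38 to 8.42) lay within the range of the controls (8.34 to 8.55). Fewer differentiated adipocytes may contribute, but a fall of about 1 SE cannot be told from the spread between libraries, so this test cannot decide. Controls shared by all knockout groups and a real effect on these genes stay open.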

How the results depend on the processing

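Fits with a tissue score as covariate and fits without several libraries at once were chosen after seeing the data; the other alternatives were planned. Both overexpression comparisons and the contrast between them kept their counts of genes within 1.5 times under all alternatives run. For each comparison with the vector these included a fit with a single vector library, whose spread was taken from the other groups. RLE size factors moved no count by more than 1.5 times. Where a count or a call changed, the cause was not tested unless given.

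With the correlation between genes estimated per list, the thermogenic medians stayed as they were but no longer passed after Runx1 overexpression (log2 -1.18), Runx2 overexpression (log2 -2.15), in Runx1 knockout cultures (log2 0.090), in Runx1 knockout iWAT (log2 1.18), Runx2 knockout iWAT (log2 1.60) and HFD iWAT (log2 -0.52), at camera adjusted p of 0.13 to 0.75. Of the other lists 4 passed in place of 112, with fry 85 and with the block 114. Of the gene sets carried over, 1 passed in place of 8, and 12 with no fold minimum. In Runx1 knockout cultures the thermogenic list also missed the threshold without Ucp1 (log2 0.085, camera adjusted p = 0.070) and with no count filter (log2 0.097, camera adjusted p = 0.061), within a range of 0.0072 to 0.13 over its alternatives.

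DESeq2 called more genes in several comparisons: 220 and 197 in the Runx1 and Runx2 knockout cultures, 1913 and 1690 for the double against these, 207 away from additivity, 2286, 1039 and 517 in Runx1, Runx2 and HFD iWAT, and 1378 and 1618 for the differences between iWAT tables. For Runx2 without the IDR it called fewer, 362 against 512 with edgeR. The genes of the deposited lists that passed numbered 648 with edgeR and 721 with DESeq2. Without the count filter 13 genes departed from additivity. Fits of the compared groups alone, which estimate the spread from fewer libraries, gave 195, 105 and 379 genes in the Runx1, Runx2 and double knockout cultures and 7 and 31 for the double against the single knockouts.

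The replicate numbers did not pair the libraries, with correlations of -0.265 to 0.413 between residuals of the same number, so a block by number removes degrees of freedom and no pairing. With this block 32 and 12 genes passed in the Runx1 and Runx2 knockout cultures, 1 away from additivity, 744 and 206 in Runx1 and HFD iWAT, 261 for the difference between these and 8 for Runx2 against Runx1. Lep turned from log2 -0.035 to 0.095 under HFD, uncalled in both.

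With a B cell score as covariate 584 genes passed in Runx1 knockout iWAT, 80 in Runx2 knockout iWAT and 0 under HFD (1103 at unadjusted p < 0.05). The HFD thermogenic median turned to log2 2.59 (camera adjusted p = 3.9e-05), and Runx1, Runx3 and Ucp1 turned to log2 4.09, 5.64 and 24.19, all uncalled. The score separates the HFD groups without overlap, so it leaves little of the genotype effect to estimate, and the median of all genes was log2 0.15. With a skeletal muscle score 230 and 1531 genes passed in Runx1 and Runx2 knockout iWAT. Without the 3 libraries rich in muscle transcripts 415 passed in Runx1 knockout iWAT. Adipoq there, uncalled throughout, was at log2 0.0021 but at -0.014 with RLE size factors and with DESeq2, -0.14 with the B cell score and -0.17 with the muscle score. Fabp4 was at log2 0.050 after Runx1 overexpression without the libraries rich in cardiac transcripts.

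With single libraries left out, counts ranged from 4 to 28 in Runx1 knockout cultures, 0 to 9 in Runx2 knockout cultures, 1050 to 3584 in double knockouts, 176 to 1952 and 205 to 1768 for these against the Runx1 and Runx2 knockouts, and 0 to 218 away from additivity. In iWAT they ranged from 99 to 1381 (Runx1), 0 to 6354 (Runx2), 120 to 394 (HFD), 308 to 833 (HFD minus other) and 3 to 4173 (Runx2 minus Runx1), and for Runx2 without the IDR from 242 to 1214. Fewer libraries cost power. Counts above the full ones may come from single libraries that widen the spread, which was not tested. For Runx2 without the IDR each such fit also had a single library in a group. Thermogenic medians ranged from log2 0.090 to 0.17 in Runx1 knockout cultures, 0.24 to 0.50 in double knockouts, -0.81 to -0.14 under HFD and -0.029 to 0.19 for Runx2 without the IDR.

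Uncalled genes near no change turned sign in such fits: Adipoq (log2 -0.13 to 0.23), Dio2 (-0.19 to 0.45) and Plin1 (-0.049 to 0.27) in Runx1 knockout iWAT, Adipoq (-0.35 to 0.19) and Lep (-0.39 to 0.42) under HFD, Plin1 (-0.33 to 0.039), Runx1 (-0.44 to 0.29) and Runx2 (-0.16 to 0.12) in double knockouts, Runx1 (-0.23 to 0.49) in Runx1 knockout cultures, Runx2 (-0.12 to 0.13) in Runx2 knockout cultures, Fabp4 (-0.11 to 0.072) after Runx1 overexpression and Ppargc1a (-0.35 to 0.0020) after Runx2 overexpression. Of the genes given in the report that passed, none but Runx3 under HFD changed sign in an alternative run here. At this depth and number of libraries a 2-fold change was recovered for 12% of simulated genes in Runx2 knockout iWAT and 88% for Runx2 without the IDR.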

Other observations

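All tests in this part were chosen before the data were examined, except the sums of cardiac and neuron genes, whose lists were chosen after seeing the data.

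In the overexpression table, cardiac genes such as Myh6 reached 36.0 and 154 CPM in control replicates 1 and 2 and 630 CPM in RUNX1 replicate 3. The same RUNX1 library had 68.4 CPM of neuron genes, against 0 to 4.14 CPM in the other 8. Of 8 cardiac genes tested, 0 were called by edgeR in either overexpression comparison. Libraries of 1 group differed in this by more than the groups did.

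B cell genes summed to 1931 to 2679 CPM in the Runx1 iWAT table, 229 to 628 CPM in the HFD controls and 7.47 to 9.77 CPM in the HFD knockouts.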
